A study of Mus musculus with 14 samples.

How the data were processed

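Total RNA was isolated from mouse colon organoids with a column kit, and 100 ng per sample went into a library kit that does not mark strand (TruSeq RNA v2), per the labels' protocols. Doxycycline was added at 1 µg/ml 1 day after passage. The medium held 100 ng/ml noggin, and 50 ng/ml EGF for the Apc organoids only. Each of the 14 libraries has a table of 116945 mouse transcripts. The authors deposited estimated counts and TPM per transcript with its length and effective length, per the file headers. These were made with Salmon 0.14.1 on mm10, per the submitters' processing notes. The release of the transcript reference and any strand or bias option are not given in the sources used here. The TPM values deposited keep no depth and entered no test, and the effective lengths were used only in an alternative.

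Estimated counts were summed per gene through the GENCODE M21 annotation (GRCm38) by transcript ID without its version. Of the transcripts 116023 matched a gene and 922 did not, and 0.207 to 0.254% of reads per library had no gene. Gene IDs that share a symbol were summed, which concerned 19 symbols with reads on more than 1 ID, a step chosen after the tables were seen. Sums were rounded to whole numbers. Totals were 14221712 to 20206994 reads per library. Estimated counts split reads among similar transcripts, so values of near-identical copies and of single transcripts are less certain than gene sums. Genes on opposite strands that overlap share reads in the same way.

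Groups follow the genotype, time and doxycycline given in the labels. All 14 libraries were fitted together in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with a mean per group, TMM scaling, filterByExpr and the quasi-likelihood F test on 7 residual degrees of freedom. Benjamini-Hochberg adjusted p-values were read at 0.05 over 13946 genes. Fold changes are model estimates, and CPM values are counts scaled to the TMM library size. Comparisons were each Apc time against 0 h, neighbouring times, any time, AKP doxycycline against control, the AKP response minus the Apc 72 h response, and AKP control against Apc 0 h. The AKP and Apc responses share no control library. A gene at 0 reads in a group was set against a floor of 3 counts over the group, and 1 to 3 reads gave a ratio with an exact 95% interval. Such floors and intervals cover counting error only, since reads are not independent molecules.

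The groups, designs, lists, the rule for named genes and most alternatives were set before the data were examined. Alternatives added later are named below, where the dependence on processing is described. Named were 17 single genes, per list up to 4 members with the smallest adjusted p (or 2 with the highest mean where none passed), and per comparison the 5 largest rises and 5 largest falls above an average log2 CPM of 3 with no overlap between libraries. The condition of no overlap was not applied to the difference of responses. The 25 lists covered YAP/TAZ targets, crypt base columnar stem cells, Wnt/beta-catenin targets, fetal and regenerating epithelium, AP-1 and immediate early genes, actin cytoskeleton and serum response factor targets, epithelial-mesenchymal transition, absorptive, goblet, enteroendocrine, tuft and Paneth cells, squamous epithelium, proliferation, p53 targets, interferon response, ATF4 and unfolded protein response, cholesterol synthesis, ERK feedback, glycolysis and hypoxia, heat shock, mitochondrially encoded genes, and fibroblast, immune and endothelial markers. The stem cell and Wnt lists share 8 genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists that had tested members. List tests between neighbouring times were added after the data were seen. Member counts are given over all genes and adjusted over the list alone.

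Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a stricter filter (CPM of at least 1 in 4 libraries), offsets from effective lengths, fits on the compared groups or 1 genotype alone, a replicate block, and leaving out each library. On simulated counts with 67, 67 and 66 genes changed by 1.5-, 2- and 4-fold, the AKP comparison (13436 genes) recovered 71.6%, 88.1% and 97% of them, with 6.1% false calls. For Apc 72 h (13426 genes) these were 67.2%, 88.1% and 100%, with 2.1% false, and for the difference of responses (13438 genes) 44.8%, 71.6% and 90.9%, with 7% false. The simulated groups had equal means apart from these genes and a shifted list in a single group, all drawn above a low average level. In the data 54.2% (AKP) and 69.1% (Apc 72 h) of genes changed, so these rates need not hold there. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.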

Results

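Transcript abundance was measured by RNA sequencing in mouse colon organoids, which are epithelial cultures grown in Matrigel. Organoids lacking Apc carried a doxycycline-inducible activated Yap transgene (tetO-YapS127A with rtTA, the doxycycline-dependent activator) and were taken after 0, 12, 24, 72 and 96 h of 1 µg/ml doxycycline. Organoids lacking Apc and p53 and carrying the KrasG12D allele, called AKP below, had tetO-Yap5SA and were taken at 72 h untreated or with doxycycline. Yap is the transcriptional coactivator that the Hippo pathway restrains, and the comparisons ask what its activation does in each line. The 14 libraries made 7 groups of 2, with 14221712 to 20206994 estimated reads each. The labels give replicate numbers but do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Set against read-counting error alone, the spread between replicates gave a chi-square per degree of freedom of 3.05 (Apc 96 h) to 15.3 (AKP control), which does not tell its source. The first principal component held 43.1% of the variance and the next 31.4%.

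The targeted genes were examined first. Yap1 (ENSMUSG00000053110.13, GRCm38 chromosome 9, 7931999 to 8004596, minus strand) stood at 146.5 ± 2.53 CPM (SD, n = 2) in Apc organoids at 0 h. It reached 370.3 ± 4.93 CPM at 12 h and 446.1 ± 5.07 CPM at 24 h, then 224.8 ± 9.71 CPM at 72 h and 213.2 ± 0.381 CPM at 96 h. In AKP organoids it was 177.6 ± 5.43 CPM in controls and 378.3 ± 25.5 CPM with doxycycline, a 2.13-fold rise (adjusted p = 5.77e-10, edgeR). Whether the transgenes are mouse or human cDNA is not stated, and reads of transgene and endogenous Yap1 cannot be separated in these files, so these values are no direct measure of either. Most of the reads gained at 12 and 24 h and in AKP organoids with doxycycline were assigned to a single short annotated Yap1 transcript of 1432 bases, ENSMUST00000173085.7, whose 3′ UTR has 373 bases against 2501 bases in the main long transcripts. Its level was 0.23 ± 0.33 RPM (reads scaled to the library total, SD, n = 2) at 0 h, 190.9 ± 6.84 at 12 h, 248.1 ± 4.26 at 24 h, 44.7 ± 1.44 at 72 h and 33.6 ± 0.75 at 96 h. In AKP organoids it was 3.92 ± 5.55 in controls and 202.9 ± 22.2 with doxycycline. The long transcript of 4171 bases had group means of 90.2 to 119 RPM. Trp53, which encodes p53 (chromosome 11, 69580359 to 69591873), was at 235.7 ± 8.71 CPM in Apc organoids at 0 h and 9.98 ± 0.00107 CPM in AKP controls. The files give no measure of the edited Apc or Kras alleles.

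**Figure D1:**
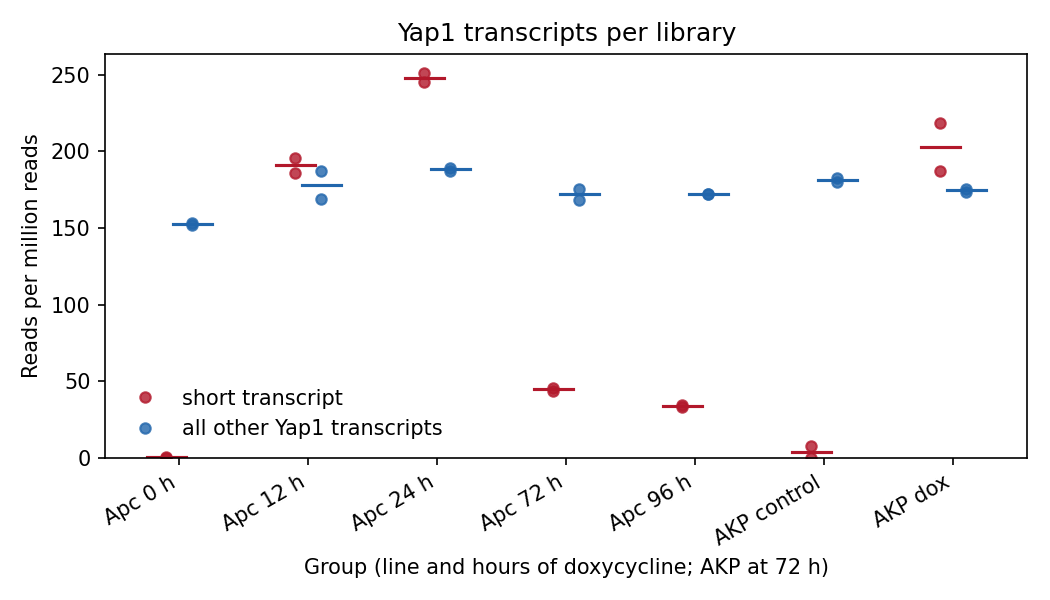
RPM (scaled reads, vertical axis) assigned to the short Yap1 transcript (red) and to all other Yap1 transcripts together (blue), by group. Points are the 2 libraries of a group and short lines are their mean. The short transcript has its highest mean, 248.1 RPM, in Apc organoids at 24 h.

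The early response was read from Apc organoids at 12 h against 0 h. Of 22 known YAP/TAZ target genes 12 were higher, 0 lower and 10 did not pass over all genes tested, and 15 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). Ankrd1 rose 2.57-fold (log2 1.36 ± 0.15 SE, n = 2 per group), Ccn1 2.05-fold (1.04 ± 0.08), Amotl2 1.94-fold (0.96 ± 0.06) and Crim1 1.51-fold (0.60 ± 0.09). All 15 genes of cholesterol synthesis and uptake rose, by either adjustment and with a median log2 change of 0.96 (adjusted p = 0.0636 with an estimated correlation). Among them Idi1 rose 2.40-fold (1.26 ± 0.08) and Mvd 2.27-fold (1.18 ± 0.11), and Ldlr, the LDL receptor, rose 1.85-fold (0.89 ± 0.08). Of 22 proliferation genes 15 were higher and 0 lower (20 and 0 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation), with Mki67 1.31-fold (0.39 ± 0.05) and Rrm2 1.43-fold (0.52 ± 0.09) higher.

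Of 15 immediate early and AP-1 genes 7 were lower and 1 higher at 12 h (8 and 1 adjusted over the list alone, adjusted p = 0.157 with an estimated correlation). Jun fell 2.66-fold (log2 -1.41 ± 0.07), and Klf4 and Fosl1 each fell 1.75-fold (-0.81 ± 0.06 and -0.81 ± 0.13), while Maff rose 1.76-fold (0.81 ± 0.12). Of the p53 targets 6 of 17 were lower and 0 higher (8 and 0 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation), led by Trp53inp1 (-1.37 ± 0.18). Squamous epithelial genes were lower for 4 of 10 and higher for 1 (6 and 1 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation), with Krt16 at -2.51 ± 0.45. Of crypt base columnar genes 2 of 22 were higher and 4 lower (3 and 4 adjusted over the list alone). Wnt/beta-catenin targets were higher for 2 of 23 and lower for 5 (2 and 6 adjusted over the list alone). Camera called neither list (adjusted p of 0.66 and 0.258). Lgr5, the marker of crypt base columnar stem cells, fell 1.77-fold (-0.82 ± 0.15, adjusted p = 0.00154, edgeR) and Rnf43 1.26-fold (-0.33 ± 0.06), the latter with adjusted p = 0.0631 under effective length offsets. Slc12a2 rose 1.33-fold. Ascl2 and Axin2 gave log2 changes of 0.06 ± 0.14 and 0.04 ± 0.08, with adjusted p of 0.809 and 0.778, and the values turned to -0.02 and -0.06 with effective length offsets. Ascl2 was also at -0.03 without the second 0 h library. Among the largest changes, Ccl20 rose 8.91-fold and Crct1 10.8-fold, and Prdm1 (-2.59 ± 0.43), Sbsn (-2.44 ± 0.16), Trib3 (-2.41 ± 0.30) and Aldh1a3 (-2.09 ± 0.18) fell. The Crct1 fold is uncertain, since this gene had few reads at 0 h.

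Over all genes, 2258 of 13946 changed at 12 h (1251 higher, 1007 lower). With DESeq2 the split was 1377 higher and 693 lower. The count was 1261 and 1018 without the first or second 0 h library, 1077 and 1120 without the first or second 12 h library, 1404 with length offsets, and 3729 in a fit on these 4 libraries alone. The camera test called 7 lists at a preset correlation, and 0 with an estimated correlation (7 at an unadjusted p under 0.05). Among the 7 were absorptive colonocyte genes, 2 of 7 higher and 0 lower by either adjustment (adjusted p = 0.113 with an estimated correlation). The absorptive call also ended without any 1 of the 14 libraries (adjusted p from 0.0596 to 0.246) and with no low-count filter (0.871), and the squamous call with no low-count filter (0.0672).

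At 24 h against 0 h the YAP/TAZ targets were higher for 14 of 22 and lower for 2, by either adjustment (adjusted p = 0.10 with an estimated correlation). Axl, a receptor tyrosine kinase, rose 16.1-fold (log2 4.01 ± 0.32), Ankrd1 4.51-fold (2.17 ± 0.14), Amotl2 2.56-fold (1.36 ± 0.06) and Ccn1 2.40-fold (1.26 ± 0.08). Lgr5 fell 3.24-fold (-1.70 ± 0.16, adjusted p = 1.61e-06, edgeR), together with Rnf43 (-0.78 ± 0.06) and Cldn2 (-1.30 ± 0.13). Of crypt base columnar genes 7 of 22 were lower and 2 higher, by either adjustment, and of Wnt/beta-catenin targets 7 of 23 were lower and 2 higher (10 and 3 adjusted over the list alone). The adjusted p was 0.14 for both lists with an estimated correlation. Goblet cell genes were lower for 7 of 9 and higher for 0 (8 and 0 adjusted over the list alone, adjusted p = 0.405 with an estimated correlation). Enteroendocrine genes were lower for 3 of 4 and higher for 0, by either adjustment (adjusted p = 0.10 with an estimated correlation). Camera did not call Paneth cell genes, 3 of 6 lower and 1 higher (4 and 1 adjusted over the list alone, camera adjusted p = 0.0687), or tuft cell genes, 1 of 6 lower and 0 higher by either adjustment (0.445). Spink4 fell 11.6-fold (-3.54 ± 0.43), Tff3 5.37-fold (-2.42 ± 0.42), Cpe 5.17-fold (-2.37 ± 0.17) and Lyz1 7.59-fold (-2.92 ± 0.40). Lyz1 reads resemble those of Lyz2, so their assignment is uncertain. Lyz2 was at most 0.0561 CPM in any library, which argues against a shift of reads to Lyz2 as the source of this fall.

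All 15 cholesterol genes were higher at 24 h by either adjustment, with a median log2 change of 1.26 (adjusted p = 0.0716 with an estimated correlation). Genes of the ATF4 and unfolded protein response were higher for 7 of 14 and lower for 2, by either adjustment (adjusted p = 0.14 with an estimated correlation), led by the serine synthesis enzyme Psat1 (2.75-fold, log2 1.46 ± 0.06), Mthfd2 (1.82-fold) and Asns (1.55-fold). Proliferation genes were higher for 15 of 22 and lower for 0 (17 and 0 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation), with Cdc20 1.61-fold and Plk1 1.49-fold higher. Glycolysis and hypoxia genes were higher for 9 of 15 and lower for 0, by either adjustment (adjusted p = 0.543 with an estimated correlation), and Pfkp rose 1.86-fold. Ccl20, an epithelial chemokine, rose 42.7-fold (5.42 ± 0.23), and Aldh1a3 (-3.30 ± 0.19) and the glutathione transferase Gsta1 (-2.78 ± 0.13) fell.

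In total 4421 genes changed at 24 h (2389 higher, 2032 lower), and 2686 without the second 0 h library, 2915 without the first 24 h library and 2820 without the second. Camera called 10 lists, and 0 with an estimated correlation (8 at an unadjusted p under 0.05). Among the 10 were squamous genes, 6 of 10 lower and 1 higher by either adjustment (adjusted p = 0.142 with an estimated correlation). The stem cell call also ended without the second 0 h library (adjusted p = 0.0516) or the second 24 h library (0.0703), with no low-count filter (0.0603) and with effective length offsets (0.0603). The squamous call also ended without the first 0 h library, either 12 h library, either 24 h library or either AKP doxycycline library (0.0517 to 0.091), with no low-count filter (0.163), with a stricter filter (0.0545) and with a replicate block (0.0553). Against 12 h, 961 genes differed (593 higher, 368 lower), and 246 to 356 when any library of either group was left out: 308 and 246 without the first or second 12 h library and 356 and 305 without the first or second 24 h library. Without the first or second AKP control library it was 1469 and 1475, with effective length offsets 473, with no low-count filter 1463 and in a fit on these 4 libraries alone 2004. Between 12 and 24 h 10 of 14 ATF4 and unfolded protein response genes rose (12 adjusted over the list alone). At 12 h against 0 h, 4 members of this list had been higher and 6 lower by either adjustment. Crypt base columnar genes were lower for 4 of 22 and higher for 1 (8 and 1 adjusted over the list alone). The camera adjusted p was 0.0455 for each with an estimated correlation, and Lgr5 fell by 0.87 on the log2 scale (adjusted p = 0.00543).

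By 72 h all 22 proliferation genes fell in Apc organoids, by either adjustment, with a median log2 change of -2.05 (adjusted p = 0.038 with an estimated correlation). Mki67 went from a mean of 417.3 CPM at 0 h to 62.6 ± 2.43 CPM (SD, n = 2), a 6.67-fold fall (log2 -2.74 ± 0.06 SE, adjusted p = 2.83e-13, edgeR), and the replication licensing genes Mcm5 and Mcm6 fell 11.6-fold and 4.93-fold. YAP/TAZ targets were higher for 14 of 22 and lower for 2, by either adjustment (adjusted p = 0.286 with an estimated correlation): Axl 86.4-fold (6.43 ± 0.26), Tgfb2 12.6-fold (3.65 ± 0.15), Nt5e 10.3-fold (3.37 ± 0.15), Ankrd1 6.68-fold, Ccn1 3.35-fold and Ccn2 1.87-fold. Of crypt base columnar genes 12 of 22 were lower and 6 higher (12 and 7 adjusted over the list alone). Smoc2 fell 165-fold (-7.37 ± 0.39), Lgr5 4.40-fold (-2.14 ± 0.17), Ascl2 3.02-fold (-1.60 ± 0.15), Cdca7 3.18-fold and Axin2 1.27-fold, while Tnfrsf19 rose 2.88-fold. Wnt/beta-catenin targets were lower for 14 of 23 and higher for 5, by either adjustment, and Cldn2 fell 10.4-fold. Camera did not call either of these lists at 72 h (adjusted p = 0.176 for both).

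Genes of fetal and regenerating gut epithelium were higher for 16 of 25 and lower for 5 at 72 h, by either adjustment (adjusted p = 0.30 with an estimated correlation). Anxa5 rose 4.55-fold (log2 2.18 ± 0.05), Il33 4.04-fold, Clu 2.42-fold (1.28 ± 0.07), Ly6a 2.13-fold (1.09 ± 0.06) and Anxa1 1.20-fold, while Plaur fell 2.65-fold. All 15 glycolysis and hypoxia genes rose, by either adjustment, with a median log2 change of 2.64 (adjusted p = 0.30 with an estimated correlation). The pH-regulating carbonic anhydrase Car9 went from 15.9 ± 0.36 to 322.4 ± 5.16 CPM, and Aldoa rose 6.22-fold, Pfkp 5.87-fold, and the lactate exporter Slc16a3 96.9-fold (6.60 ± 0.56). Interferon response genes were higher for 11 of 14 and lower for 0, by either adjustment (adjusted p = 0.322 with an estimated correlation), with Irf7 7.33-fold, Stat2 3.14-fold and Bst2 3.03-fold higher. Of p53 targets 14 of 17 were higher and 3 lower, by either adjustment (adjusted p = 0.289 with an estimated correlation), and the pro-apoptotic Bbc3 and Pmaip1 rose 4.28-fold and 3.85-fold. ATF4 and unfolded protein response genes were higher for 11 of 14 and lower for 0 (Ddit3 5.84-fold), and all 15 cholesterol genes were above 0 h (Fdps 3.81-fold, Mvd 3.78-fold), by either adjustment. The adjusted p was 0.30 and 0.319 for these lists with an estimated correlation.

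Among squamous epithelial genes 3 of 10 rose and 7 fell at 72 h, by either adjustment: Ivl rose 32.7-fold and Sprr1a 20.3-fold, while Krt6a (log2 -6.78) fell, and Lor fell 12.5-fold. Of 7 tested absorptive colonocyte genes 4 rose and 1 fell, by either adjustment, with Krt20 16.3-fold (log2 4.03 ± 0.45) and Car2 4.03-fold (2.01 ± 0.07) higher. Among Paneth cell genes 5 of 6 were lower and 1 higher by either adjustment, the latter Mmp7 (12.9-fold). Camera called none of these 3 lists (adjusted p of 0.434, 0.154 and 0.593), and 69.1% of all genes tested changed at 72 h. Ang4 had 0 reads at 72 h and was at least 51.6-fold lower, against a floor of 3 counts over the group, though it belongs to a family of similar genes. Serpine1 rose 20.3-fold, Vim 7.21-fold and Fn1 2.25-fold. Klf4 and Fosl1 fell 3.53-fold and 9.42-fold, and Klf6 gave a log2 change of -0.12 ± 0.09 with adjusted p = 0.256, and 0.0208 without the first or the second AKP control library. The intestinal transcription factors Myb and Cdx1 fell 34.0-fold and 25.3-fold, and Crct1, a gene of the cornified envelope region, rose from 0.131 ± 0.185 to 45.2 ± 1.32 CPM. Of the markers of other cell types, Cd68 rose 18.8-fold and Csf1r 3.49-fold.

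In total 9640 genes changed at 72 h (4729 higher, 4911 lower, and 4792 and 4259 with DESeq2), 4156 of them at least 2-fold. No untreated Apc organoids at 12 to 96 h were analysed here, so time in culture and doxycycline are not separated from the transgene. Camera called 10 lists, and with an estimated correlation only proliferation held. That adjusted p was 0.286 for epithelial-mesenchymal genes (4 of 8 higher and 1 lower by either adjustment) and 0.163 for the 3 immune genes tested (2 higher, or 3 adjusted over the list alone). The epithelial-mesenchymal call also ended without any single library except the first 72 h library and the AKP control libraries (adjusted p from 0.0538 to 0.132), with RLE factors (0.0534), with no low-count filter (0.307) and with effective length offsets (0.0566). The immune call ended with no low-count filter (0.139). Against 24 h, 9390 genes differed (4690 higher, 4700 lower). In that step all 22 proliferation genes fell by either adjustment (median log2 change -2.37, adjusted p = 0.0144 with an estimated correlation). Yap1 itself fell 1.98-fold (adjusted p = 1.2e-09, edgeR).

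At 96 h against 0 h all 22 proliferation genes fell, by either adjustment, with a median log2 change of -3.54 (adjusted p = 0.00476 with an estimated correlation). Mki67 fell 25.5-fold (log2 -4.67 ± 0.06), Ccnb1 24.1-fold and Birc5 19.4-fold. Of crypt base columnar genes 12 of 22 were lower and 6 higher, by either adjustment, and camera did not call the list (adjusted p = 0.205). Lgr5 fell 6.94-fold (-2.79 ± 0.18), Ascl2 6.09-fold (-2.61 ± 0.17) and Smoc2 345-fold (-8.43 ± 0.43). YAP/TAZ targets were higher for 16 of 22 and lower for 4 (17 and 4 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation), and Ccn1 rose 4.02-fold. Clu rose 4.09-fold (2.03 ± 0.07), Ly6a 2.28-fold (1.19 ± 0.06) and Krt20 29.9-fold, and Hif3a, Glipr2 and Loxl2 rose 108-fold, 84.5-fold and 81.4-fold. Myb (log2 -7.57) fell, and the adhesion gene Chl1 fell 65.6-fold.

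In total 9657 genes changed at 96 h (4733 higher, 4924 lower, and 4744 and 4363 with DESeq2). Camera called 10 lists, and with an estimated correlation only proliferation held. That adjusted p was 0.353 for fetal (17 of 25 higher, 6 lower), actin (9 of 18 higher, 3 lower), interferon (13 of 14 higher) and glycolysis genes (15 of 15 higher), all by either adjustment. It was 0.191 for p53 targets (13 of 17 higher, 3 lower), 0.182 for epithelial-mesenchymal genes (4 of 8 higher, 1 lower), 0.437 for cholesterol genes (15 of 15 higher) and 0.146 for the 3 immune genes (3 higher), by either adjustment. The actin call also ended without the first 0 h library (0.0518) and with a replicate block (0.0506), the epithelial-mesenchymal call without the second 0 h library (0.0549) and with no low-count filter (0.208), and the immune call with no low-count filter (0.166). From 72 to 96 h 2418 genes differed (934 higher, 1484 lower, and 702 and 1399 with DESeq2). That count was 1080 without the first 72 h library, 975 and 1266 without the first or second 96 h library, and 1456 with length offsets (422 higher, 1034 lower). All 22 proliferation genes fell further in this step, by either adjustment (median log2 change -1.64, adjusted p = 0.000395 with an estimated correlation). Over the 4 times, 11262 genes differed from 0 h at some time in a joint F test.

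**Figure D2:**
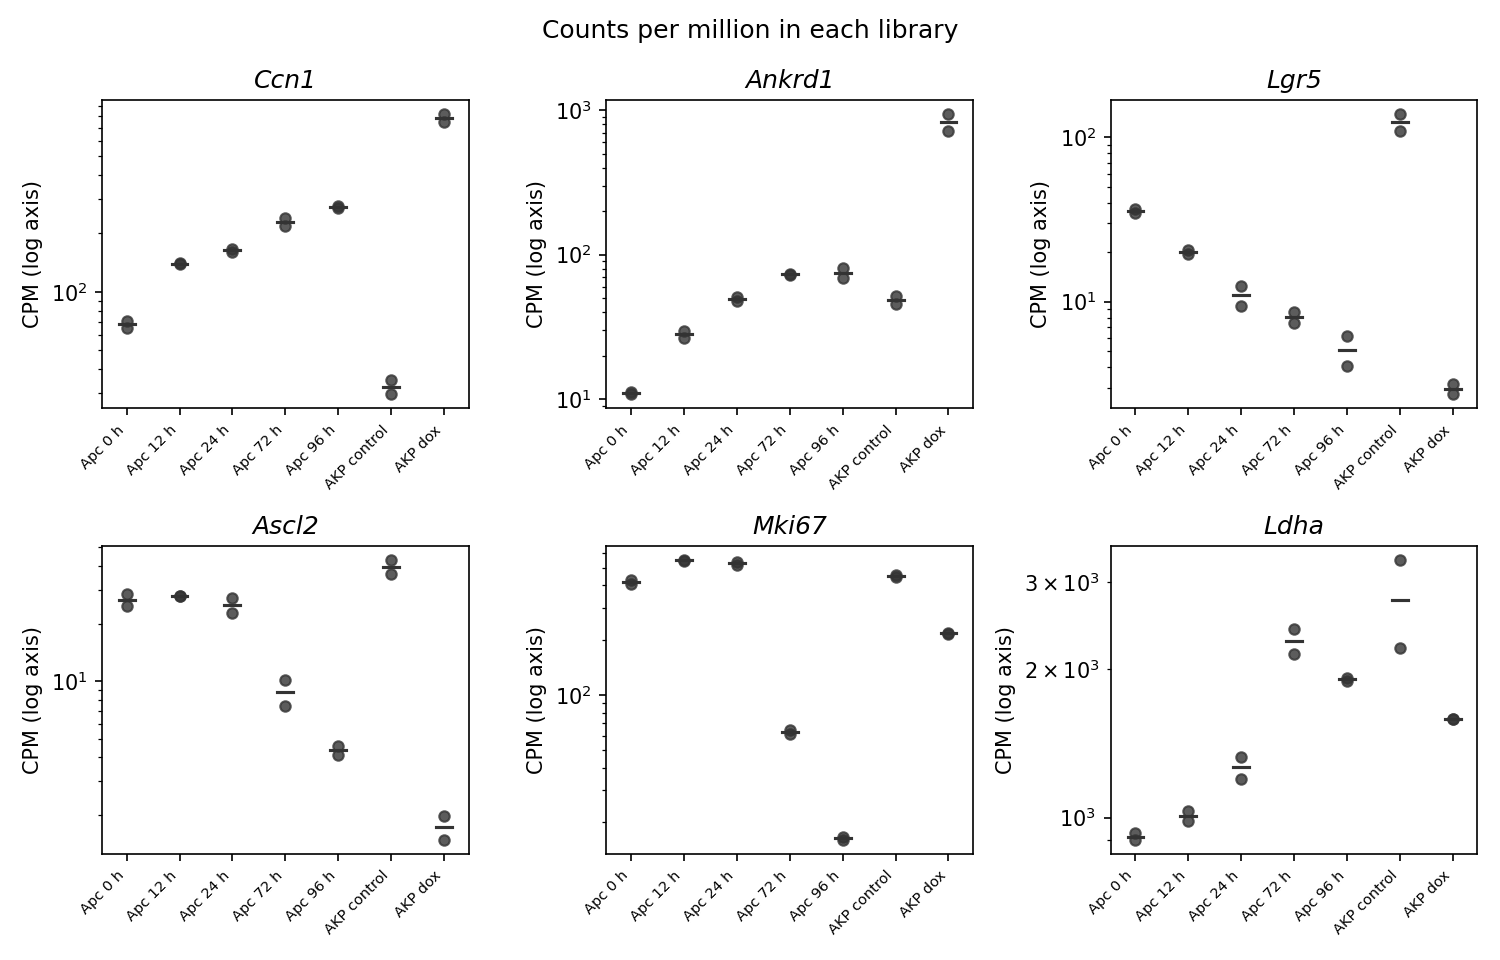
CPM of 6 genes in each of the 14 libraries, on log axes. Points are libraries and short lines are group means; for Mki67 the mean goes from 417.3 CPM in Apc at 0 h to 16.4 CPM at 96 h, and for Lgr5 from 123.4 CPM in AKP controls to 2.95 CPM with doxycycline.

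In AKP organoids at 72 h, YAP/TAZ targets were strongly higher with doxycycline than in untreated controls. No organoids without a Yap transgene were analysed here, so doxycycline itself is not separated from the transgene in AKP organoids either. Of the 22 genes 19 were higher and 1 lower, by either adjustment, with a median log2 change of 2.18 (camera adjusted p = 0.00135 with an estimated correlation). Ccn1 (chromosome 3, 145646976 to 145649981) went from 32.4 ± 3.85 CPM (SD, n = 2) in controls to 782.6 ± 50.8 CPM, a 24.0-fold rise (log2 4.59 ± 0.09 SE, adjusted p = 1.72e-14, edgeR). Axl rose 118-fold (6.89 ± 0.20), Ankrd1 16.9-fold (4.08 ± 0.12), Amotl2 by 3.70 ± 0.06 on the log2 scale and Ccn2 4.81-fold (2.27 ± 0.12). All 18 actin cytoskeleton and serum response factor target genes rose, by either adjustment (median 1.30, adjusted p = 0.00135 with an estimated correlation), among them Thbs1 4.43-fold, Actn1 3.53-fold, Itgb1 2.98-fold and Tpm1 2.48-fold. Epithelial-mesenchymal genes rose for 5 of 8 and fell for 0 (6 and 0 adjusted over the list alone; adjusted p = 0.0451 with an estimated correlation), with Serpine1 18.9-fold, Vim 8.01-fold and Fn1 1.99-fold higher.

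Stem cell and Wnt genes fell in the same AKP comparison. Of crypt base columnar genes 18 of 22 were lower and 1 higher (19 and 1 adjusted over the list alone; adjusted p = 0.00135 with an estimated correlation). Lgr5 (chromosome 10, 115450311 to 115587780) went from 123.4 ± 19.5 to 2.95 ± 0.303 CPM, a 41.6-fold fall (log2 -5.38 ± 0.18, adjusted p = 4.19e-12). Smoc2 fell 154-fold (-7.27 ± 0.38), Ascl2 22.5-fold (-4.49 ± 0.19), Noxo1 13.6-fold, Ephb2 4.24-fold and Slc12a2 3.01-fold. Of Wnt/beta-catenin targets 19 of 23 were lower and 3 higher, by either adjustment (adjusted p = 0.0215 with an estimated correlation), with Cldn2 11.3-fold and Axin2 2.35-fold lower. Of proliferation genes 21 of 22 were lower and 0 higher by either adjustment, with a median log2 change of -0.57 (adjusted p = 0.241 with an estimated correlation). Mki67 fell 2.06-fold, Aurkb 1.89-fold, Birc5 1.74-fold and Mcm7 1.70-fold.

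Fetal and regenerating epithelium genes split, with 18 of 25 higher and 7 lower by either adjustment (adjusted p = 0.416 with an estimated correlation). Msln rose 5.93-fold (log2 2.57 ± 0.06), Plaur 2.82-fold, Anxa1 2.31-fold and Clu 1.30-fold, while Areg fell 4.15-fold, Spp1 3.88-fold and Ly6a 1.77-fold (-0.82 ± 0.06). Glycolysis and hypoxia genes were lower for 14 of 15 and higher for 0, by either adjustment (adjusted p = 0.762 with an estimated correlation): Egln3 fell 9.43-fold, Ankrd37 5.37-fold, Ndrg1 3.28-fold and Ldha 1.75-fold. The AKP control libraries differed from each other in this list, the second lying 0.62 above the first in the median log2 value. Of 7 absorptive genes 4 fell and 1 rose (4 and 3 adjusted over the list alone; adjusted p = 0.117 with an estimated correlation), with Vil1 3.97-fold and Car2 3.01-fold lower. Krt20 rose from 0.0969 ± 0.137 to 3.33 ± 1.35 CPM. That list call also ended without either doxycycline library (0.0738 and 0.0682), without either Apc 12 h library (0.0523 and 0.0519) and without either Apc 24 h library (0.0549 and 0.0551), and with no low-count filter (0.256).

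Other genes changed in AKP organoids without a list call. Immediate early genes split, 5 of 15 higher and 6 lower (6 and 6 adjusted over the list alone), with Dusp1 3.98-fold and Klf6 1.55-fold higher and Jun and Klf4 2.93-fold and 2.91-fold lower. The AKP control libraries differed from each other in this list, with median log2 CPM of 6.02 and 6.92. The doxycycline libraries lay between them, at 6.27 and 6.18. Among squamous genes 3 of 10 rose and 3 fell, by either adjustment, with Ivl 66.1-fold, Sprr1a 5.44-fold and Krt14 2.75-fold higher. Cholesterol genes were lower for 9 of 15 and higher for 1 (11 and 1 adjusted over the list alone), with Insig1 1.78-fold, Hmgcs1 1.69-fold and Sqle 1.58-fold lower and Ldlr 1.61-fold higher. Ifit2 rose 16.8-fold and Irf7 fell 2.92-fold within the interferon list, where 1 of 14 genes was higher and 6 lower. Median log2 CPM of the interferon list was 1.83 and 2.85 in the control libraries and 1.07 and 1.27 with doxycycline. Plk2 rose 5.25-fold within the p53 list, where 8 of 17 were higher and 5 lower. These counts were the same by either adjustment. Csf1r, the receptor for colony stimulating factor 1, went from 0.328 ± 0.0846 to 63.8 ± 2.43 CPM, while Cd68 fell 3.81-fold. Siglecg had 2 reads in the controls and 2466 with doxycycline, a ratio of 1180 with a 95% counting interval of 327 to 9780. Lrp2 rose 355-fold, Crct1 272-fold and Lce1h 208-fold, and Vipr1, Entpd8 and Vsig1 fell 82.9-fold, 81.3-fold and 41.8-fold.

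In total 7562 of 13946 genes changed in AKP organoids (3687 higher, 3875 lower, and 3438 and 3373 with DESeq2), 2646 of them at least 2-fold. Camera called 9 lists, of which 5 held with an estimated correlation: YAP/TAZ targets, crypt base columnar genes, Wnt/beta-catenin targets, actin and serum response factor genes, and epithelial-mesenchymal genes.

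**Figure D3:**
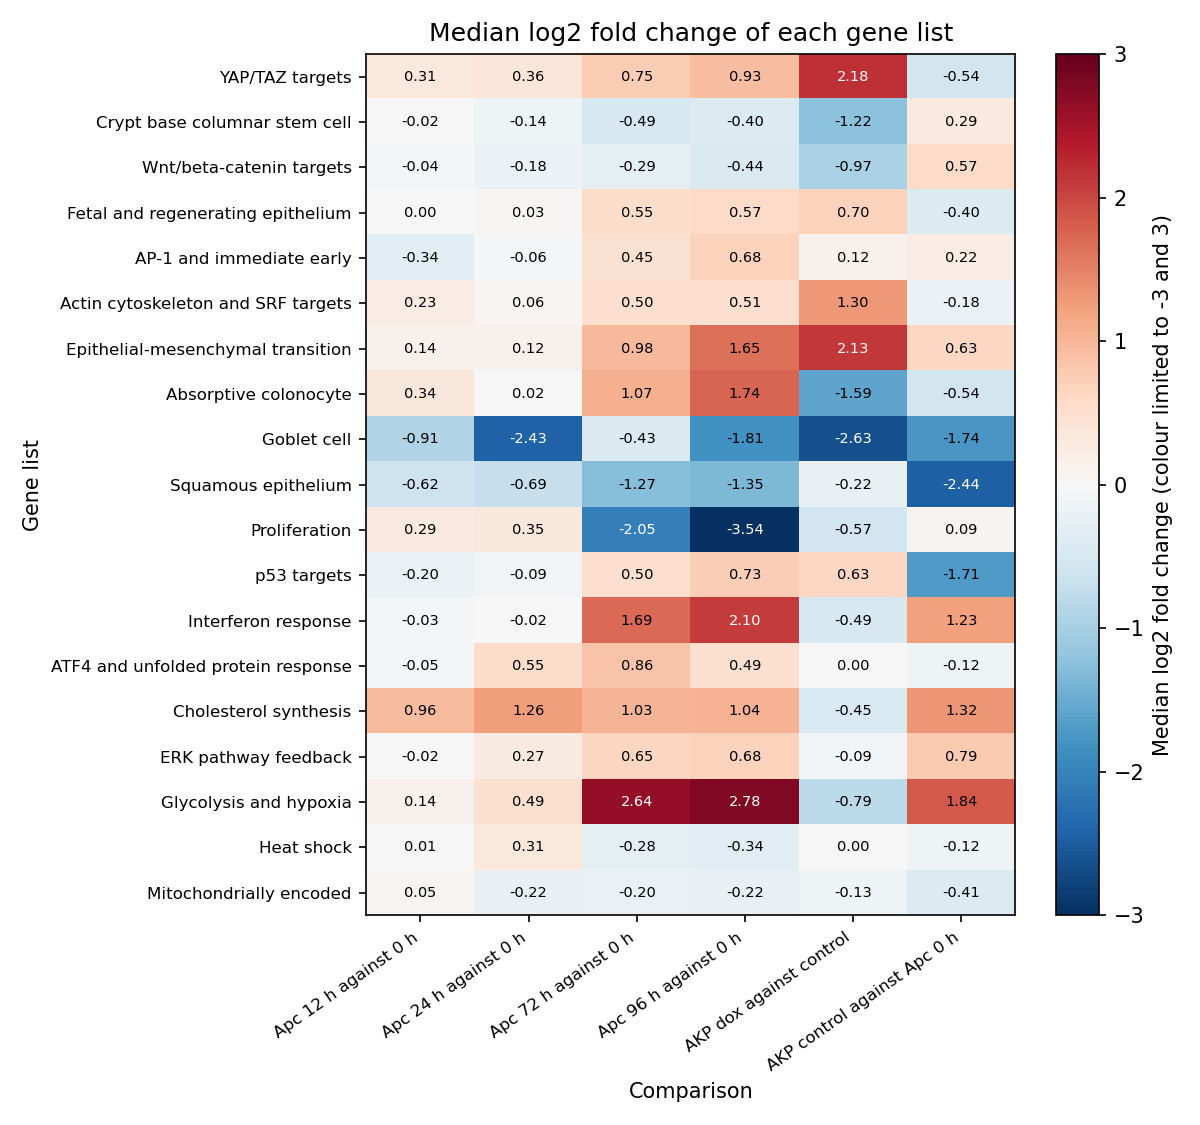
Median log2 fold change of each list with at least 7 tested genes (rows) in 6 comparisons (columns). Members at 0 reads in a group were held at a floor of 3 counts. Members at 3 or fewer counts in both groups were left out. In Apc organoids the epithelial-mesenchymal median thus reads 0.98 at 72 h and 1.65 at 96 h. Over all 8 tested genes the fitted medians were -0.1 and 0.04. Red is higher and blue lower, with the colour limited to -3 and 3; the proliferation median goes from 0.29 at 12 h to -3.54 at 96 h in Apc organoids.

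The responses of the 2 lines were compared through a difference of differences. It set AKP doxycycline against control, both at 72 h, beside Apc at 72 h against 0 h. Of 22 YAP/TAZ targets 13 had a higher response in AKP organoids, 2 a lower one and 7 did not pass (14 higher and 3 lower adjusted over the list alone, adjusted p = 0.103 with an estimated correlation). Among the single genes chosen in advance the difference in log2 change was 2.84 ± 0.11 (SE) for Ccn1, 1.37 ± 0.16 for Ccn2 and 1.34 ± 0.19 for Ankrd1. Lgr5 fell further in AKP organoids by a difference of -3.24 ± 0.26 (adjusted p = 7.08e-08, edgeR), Ascl2 by -2.89 ± 0.26 and Axin2 by -0.89 ± 0.12. Ly6a (-1.92 ± 0.08) and Clu (-0.90 ± 0.10) had a lower response in AKP organoids, and Anxa1 (0.95 ± 0.10) a higher one. Mki67 fell in both lines, and its difference of 1.70 ± 0.07 is a smaller fall in AKP organoids. Krt20 gave a difference of 0.78 ± 0.85, with adjusted p = 0.455 (edgeR). Without the second AKP control library it was 4.79, an uncertain value, since the control library left had few or no Krt20 reads. Glycolysis and hypoxia genes had a lower response in AKP organoids for all 15 members by either adjustment, with a median difference of -3.40 (adjusted p = 0.166 with an estimated correlation). Yap alleles, EGF in the medium (50 ng/ml for Apc organoids) and the kind of control differed between the lines too. Time in culture therefore enters the Apc response only.

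In all, 8443 genes differed in response (4678 higher in AKP, 3765 lower). Across the 13946 genes, the AKP and Apc 72 h log2 changes, which share no library, correlated with Pearson r = 0.248 and Spearman rho = 0.211, where genes are not independent replicates. The calls were both higher for 1844 genes against 1250.2 for independent lists, and both lower for 1813 against 1364.6. They were opposite for 861 genes (higher in AKP, lower in Apc) and 1155 genes (lower in AKP, higher in Apc), against 1298.4 and 1314. With no low-count filter r was 0.152, and without the first AKP control library 0.188.

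AKP controls were also set against Apc organoids at 0 h, a comparison in which genotype, medium, transgene and time differ together. Of the p53 targets 16 of 17 were lower and 0 higher, by either adjustment (median log2 change -1.71, adjusted p = 0.00017 with an estimated correlation). Ccng1 fell 9.62-fold (-3.27 ± 0.06), Phlda3 14.2-fold and Zmat3 4.72-fold, and Trp53 was 23.6-fold lower (-4.56 ± 0.08, adjusted p = 4.63e-15, edgeR). ERK pathway feedback genes were higher for 8 of 12 and lower for 3, by either adjustment (adjusted p = 0.257 with an estimated correlation), with Etv5 13.1-fold, Spry4 11.5-fold and Etv4 4.22-fold higher. Squamous genes were lower for 8 of 10 and higher for 1, by either adjustment (adjusted p = 0.0303 with an estimated correlation), including Krt14 7.91-fold, Lor 9.37-fold, Dsg3 6.06-fold and Krt6a 4.87-fold. Lgr5 was 3.49-fold higher (1.80 ± 0.14) and Notum 36.5-fold, while Ccn1 and Ccn2 were 2.09-fold and 2.26-fold lower. Cholesterol genes were higher for all 15 members by either adjustment (Dhcr7 3.62-fold, Mvd 3.50-fold), and glycolysis and hypoxia genes for 13 of 15, with 1 lower, by either adjustment (Vegfa 11.7-fold, Pfkp 3.74-fold). The adjusted p with an estimated correlation was 0.25 and 0.455 for these lists.

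Some genes were close to absent from either line. Dapk1 and Mgmt had 0 reads in the AKP controls and were at least 248-fold and 91.6-fold lower, against a floor of 3 counts over the group. Hoxd13 was 907-fold lower. Padi2 and Trbc1 were 354-fold and 208-fold higher. Eno1b had a log2 change of 8.64 ± 0.16, which is uncertain, since it is a near-identical copy of Eno1 and the estimated counts split their shared reads. Kras was 1.26-fold and Yap1 1.21-fold higher, and Ly6a 1.58-fold. Apc was 1.19-fold lower with adjusted p = 0.00763, 0.0555 without the second AKP control library, 0.0527 with a replicate block and 0.383 with effective length offsets. In total 7391 genes differed (3781 higher, 3610 lower, and 3210 and 3431 with DESeq2), and camera called 10 lists. With an estimated correlation the p53 and squamous lists held, and the adjusted p was 0.41 for YAP/TAZ targets (4 higher and 13 lower of 22), 0.25 for crypt base columnar genes (12 higher, 2 lower of 22) and for Wnt/beta-catenin targets (15 higher, 2 lower of 23), 0.597 for fetal genes (8 higher, 12 lower of 25) and 0.598 for mitochondrially encoded genes (0 higher, 10 lower of 13). The counts of the first 4 of these lists were the same adjusted over the list alone, and 11 mitochondrial genes were lower by it. The mitochondrial call also ended without the first AKP control library (adjusted p = 0.0679), and the fetal call with no low-count filter (0.101).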

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

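The 6 tests of explanations here were chosen only after the results were seen, while the tests of the difference between the lines were planned. The AKP response to doxycycline at 72 h and the Apc change from 0 to 72 h differed in 8443 genes by the test of the difference itself. Only the Apc change includes time in culture, so these differences cannot be put down to the lines alone. Of the gene lists, 10 differed by camera at a preset correlation and 0 with an estimated one (7 at an unadjusted p under 0.05). The median difference was 1.34 for YAP/TAZ targets (13 of 22 higher and 2 lower in AKP, 14 and 3 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation), -0.91 for crypt base columnar genes (2 higher and 14 lower of 22, either way; adjusted p = 0.0651) and -0.79 for Wnt/beta-catenin targets (3 higher and 13 lower of 23, either way; 0.166). It was 0.90 for actin and serum response factor genes (11 higher and 2 lower of 18), -2.62 for absorptive genes (1 higher and 4 lower of 7) and 1.42 for proliferation genes (21 higher and 0 lower of 22), with the same counts adjusted over the list alone and adjusted p = 0.0761 for each with an estimated correlation. It was -2.30 for interferon genes (1 higher and 12 lower of 14), -0.65 for ATF4 genes (2 higher and 10 lower of 14), -1.60 for cholesterol genes (0 higher and 14 lower of 15) and -3.40 for glycolysis and hypoxia genes (0 higher and 15 lower of 15). These counts too were the same adjusted over the list alone, and that adjusted p was 0.425, 0.425, 0.241 and 0.166. The absorptive call also ended with no low-count filter (0.235) and with a replicate block (0.066). The 1.42 for proliferation genes is a smaller fall in AKP, since their median log2 change was -0.57 there and -2.05 in Apc organoids.

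Among single genes the difference in log2 change (AKP minus Apc) was 0.47 for Yap1, -3.24 for Lgr5, -2.89 for Ascl2, -0.89 for Axin2, 2.84 for Ccn1, 1.37 for Ccn2, 1.34 for Ankrd1 and 0.75 for Klf6. It was -1.92 for Ly6a, -0.90 for Clu, 0.95 for Anxa1, 1.70 for Mki67, 0.31 for Kras and -0.60 for Trp53. For Apc it was 0.51, with adjusted p = 0.183 under effective length offsets. The largest differences among the genes that met the naming rule included 8.63 for Serpinb2, 6.22 for Adgrg2, -9.53 for Hif3a, -7.78 for Slc16a3, -7.72 for Cited1 and -7.66 for Rasa4.

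All 15 glycolysis and hypoxia genes rose in Apc organoids by 72 h, and 14 of 15 fell and 0 rose in AKP organoids with doxycycline (adjusted p of 0.30 and 0.762 with an estimated correlation). Doxycycline acting alike in both lines would need AKP organoids to rise by about the Apc median of 2.64. Their median log2 change was -0.79, so no such rise was seen. The planned difference was -3.40 in the median (SD of members 2.02) with 15 of 15 lower (camera adjusted p = 0.166 with an estimated correlation). These values cannot decide the question. The Apc change holds time in culture as well as doxycycline, and the AKP change may come from the dishes, as given below. Time in culture stays open, because untreated AKP organoids at 72 h lay 1.84 above Apc at 0 h in the median, a comparison in which genotype differs as well. Dishes that differ in oxygen or medium cannot be told apart from doxycycline in AKP organoids: the smallest gap between a control and a doxycycline library was 0.42, below the 0.62 between the control libraries. A difference in the biology of the lines remains open and untested.

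The short Yap1 transcript fell from 248.1 to 44.7 RPM between 24 and 72 h in Apc organoids. Reassignment of its reads to other Yap1 transcripts would need these to gain, and they changed by -16.3 against a loss of 203 RPM, a ratio of -0.0801 ± 0.0275 (SD), which argues against it. Whether YAP/TAZ targets follow the transcript down is open: their median log2 change from 24 to 72 h was 0.34, with 12 of 22 higher and 8 lower by either adjustment (camera adjusted p = 0.124). Transgene and endogenous Yap1 reads cannot be separated in these files, and whether the transgene is mouse or human cDNA is not stated, so the transcript is no direct measure of the transgene. The cause of the fall was not tested.

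Csf1r and Hck, best known from myeloid cells, and Siglecg, best known from B cells, rose in AKP organoids with doxycycline, to 63.8 CPM for Csf1r. Leukocytes in the cultures would bring their abundant transcripts, but 13 leukocyte genes had a median of 0.0297 CPM there, 0.000466 of the Csf1r level, and the highest was Aif1 at 0.861 CPM, which argues against leukocytes as the source. Of the 13 genes 3 passed the low-count filter and 3 are also in the immune list. Hck is in the tuft cell list, had 1 read in controls and 205 with doxycycline, a ratio of 197 with a 95% counting interval of 34.9 to 7810. A candidate explanation is expression by the organoid cells themselves, which stays a hypothesis.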

How the results depend on the processing

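Alternatives added after the data were seen were other scalings and DESeq2 for the correlation and the stricter filter for single lists; all others were planned. With effective length offsets the count of changed genes was 1404 at 12 h, 473 for 24 h against 12 h and 1456 for 96 h against 72 h. In fits on the compared groups alone it was 3729 at 12 h and 2004 for 24 h against 12 h, and with no low-count filter it was 1463 for 24 h against 12 h. The correlation of the AKP and Apc responses was 0.152 with no filter, which brings in genes with few reads. With an estimated correlation the list calls went from 7 to 0 at 12 h, 10 to 0 at 24 h, 10 to 1 at 72 h and at 96 h, 9 to 5 in AKP, 10 to 0 for the difference and 10 to 2 for AKP control against Apc 0 h. With no low-count filter 11 list calls ended, with effective length offsets 2, and with RLE factors and the stricter filter 1 each. Leaving out each library gave 1018 to 3025 genes at 12 h, 2686 to 5059 at 24 h, 246 to 1475 for 24 h against 12 h, 975 to 3145 for 96 h against 72 h, and a correlation of 0.188 to 0.285. The ranges were 8570 to 9861 at 72 h, 8727 to 9884 at 96 h, 6242 to 7767 in AKP, 7731 to 8518 for the difference and 5928 to 7556 for AKP control against Apc 0 h. A group left with 1 library was assumed to vary like the others. Ascl2 at 12 h was at -0.02 with length offsets and between -0.03 and 0.17 over left-out libraries, and Axin2 at 12 h was at -0.06 with length offsets. In fits on 1 genotype alone the count was 3004 at 12 h, 1417 for 24 h against 12 h and 6440 in AKP. The main fit, with 1 spread shared by both lines, gave 2258, 961 and 7562. The Apc counts rose with fewer samples, so the loss of samples does not explain them. Replicates differed most in the AKP controls (chi-square per degree of freedom 15.3), which enter the shared spread. Apart from what the shared spread and fewer samples or genes tested may explain, the cause was not tested. DESeq2 shared 1842 calls of direction with edgeR at 12 h, 8867 at 72 h and 6759 in AKP, with 0 opposite.

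Libraries with the same replicate number showed little shared shift in expression. The correlation of replicate differences lay between -0.045 and 0.081 within Apc groups and was -0.028 within AKP. Whether libraries with the same number came from the same culture cannot be told from these values. With the number as a replicate block the counts were 2279 at 12 h, 4391 at 24 h, 9540 at 72 h, 9574 at 96 h, 7497 in AKP, 8343 for the difference and 6214 for AKP control against Apc 0 h. Under it 3 list calls ended, with adjusted p of 0.0553 (squamous, 24 h), 0.0506 (actin, 96 h) and 0.066 (absorptive, difference), as did the call for Apc in AKP controls (0.0527). At this depth, genes under the low-count filter were not tested, among them Olfm4.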

Other observations

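The list tests between neighbouring times were chosen only after results were seen, and the other tests here were planned. Of heat shock genes 1 of 9 was higher and 4 lower in Apc organoids at 12 h (2 and 4 adjusted over the list alone), with Hspa1b 1.78-fold lower (log2 -0.83 ± 0.12, n = 2 per group), a value shared with its near-identical copy Hspa1a and so uncertain. From 12 to 24 h 6 of 9 rose and 0 fell by either adjustment (camera adjusted p = 0.0455 with an estimated correlation). Against 0 h, 6 were higher and 1 lower at 24 h by either adjustment. At 72 h 3 were higher and 5 lower by either adjustment, with the mitochondrial chaperones Hspd1 and Hspe1 2.99-fold and 1.99-fold lower, and at 96 h 4 were higher and 5 lower by either adjustment, with Hspd1 4.48-fold lower. Camera did not call the list in any comparison with 0 h (adjusted p of 0.2, 0.0622, 0.477 and 0.593 at 12, 24, 72 and 96 h).

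Tuft cell genes split at 72 h, 3 of 6 higher and 1 lower by either adjustment. Avil, a tuft cell actin-binding protein, fell 2.64-fold at 24 h, rose 3.33-fold at 72 h (log2 1.74 ± 0.19) and fell 8.05-fold in AKP organoids with doxycycline (-3.01 ± 0.26), where 2 of 6 members were higher and 1 lower. Camera called the tuft list in none of these comparisons (adjusted p = 0.593 at 72 h and 0.924 in AKP). Of 6 endothelial markers Tek and Vwf were tested. Tek had 0 reads at 72 h and was at least 3.3-fold lower than at 0 h, against a floor of 3 counts over the group, and Vwf fell by 1.48 on the log2 scale in AKP organoids (adjusted p = 0.0291, edgeR). The list counts were 0 higher and 1 lower in each, by either adjustment. None of the 9 fibroblast and smooth muscle markers passed the low-count filter.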
